A study of Mus musculus with 8 samples.

How the data were processed

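RNA was measured in lens capsules of adult C57BL/6 mice aged 6 to 8 weeks, collected 7 days after surgery, with 4 libraries from sham-operated mice and 4 from mice with an injury-induced model that the submitters call ASC and describe as a model of fibrotic cataract. Per the labels' protocols, the ASC eyes received a needle incision of the anterior lens capsule through the cornea, and the sham eyes a corneal incision that left the capsule closed. Total RNA was extracted with Trizol, poly-A RNA was selected, and libraries were made with random priming and a size selection of 370 to 420 bp, per the labels' protocols. Each replicate is described as biological; how many capsules or mice entered a library is not given in the sources used here.

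The authors deposited 1 table of read counts per gene, whole numbers that had not been normalized. Per the submitters' processing notes, the tools were CASAVA, fastp, HISAT2 version 2.0.5 and featureCounts version 1.5.0-p3. The genome build, the annotation release, whether reads were assigned by strand and how reads matching several genes were counted are not given in the sources used here. For this reason no coordinates are given, and counts of overlapping or antisense genes and of near-identical gene copies (gamma crystallins, hemoglobins, amylases, some zinc finger clusters) may mix with those of their neighbours or copies. The table held 54532 gene identifiers, every line named a gene, and all 8 count columns were used. Gene symbols were matched for 54409 identifiers, and GENCODE mouse release 21, which held 54495 of the 54532, gave gene types, GC content and transcript length.

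Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the 2 groups, which left 15857, library sizes were scaled by TMM, and each gene was tested with the robust quasi-likelihood F test of ASC against sham with no covariate. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05, and a second count took genes with at least a 2-fold change. Log2 fold changes are ASC over sham. The standard error (SE) of a log2 fold change was its size divided by the square root of the F statistic, and 95% confidence intervals used the test's degrees of freedom. Levels are edgeR's CPM, counts scaled by the TMM-adjusted library size, as mean ± SD over 4 libraries, and log2 CPM used a prior count of 2. Library totals ranged from 14420494 to 21141582 counts. Reads carried no molecular identifiers, so counting precision refers to reads, not molecules.

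Before the data were examined, 37 gene lists were fixed, covering pathways, lens cell types and other cell types the capsule preparation could hold, together with the tests and the rule for the genes named in the text. That rule took (1) the 8 largest rises and 8 largest falls among genes past the threshold with an average log2 CPM of at least 3 and no overlap between groups, leaving out model names and pseudogenes; (2) Smurf1, Smurf2, Smad1, Smad2, Smad3, Smad4, Smad5, Smad7, Acta2, Fn1, Col1a1, Tgfb1, Tgfb2, Pax6 and Foxe3 whatever their result; and (3) from each list up to 4 members (3 for secondary and cell type lists) past the threshold with the largest change and an average log2 CPM of at least 1, or else its 1 or 2 most abundant members as values. Genes named outside the rule are said to have been chosen after their values were seen.

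For each list, members past the threshold were counted, both over all genes tested and adjusted over the list alone. The 35 lists with at least 3 tested members were tested for direction against all other tested genes with camera (limma 3.58.1), with a preset inter-gene correlation of 0.01 and again with an estimated one. The same lists were tested with fry, which tests a list's genes against no change and does not compare them with other genes. Summed levels of cell type markers and other single values were compared with two-sided exact permutation tests over the 70 assignments of the 8 libraries, whose smallest p is 0.0286. The analysis was tested on counts simulated for 15480 genes from the real means, dispersions and library sizes of the 4 sham and 4 ASC libraries, with genes drawn independently of each other. It called 30.3% of genes changed 1.5-fold, 60% of those changed 2-fold and 84.6% of those changed 4-fold, with 2.6% of the calls false. The list test called the list raised by 0.5 on the log2 scale and 0 others. With independent genes this cannot show how often lists are called through correlation between genes. Nor does the 2.6% cover false calls from differences between libraries that many genes share.

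Alternatives fixed beforehand were DESeq2 1.42.0, limma-voom with sample quality weights, 3 other scalings, crystallin genes left out, 2 other low-count filters, the replicate number as a block, each library left out in turn, a fit without robust estimation, a test against a 1.5-fold change, an adjusted p threshold of 0.01, and other settings for lists and principal components. Marker levels as covariates, GC and length corrections and 2 sets of left-out libraries were added after seeing the data. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.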

Results

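Gene expression was profiled in 8 mouse lens capsule libraries, 4 from sham-operated eyes and 4 from eyes with the injury-induced ASC model, all taken 7 days after surgery. The lens capsule preparation carries the lens epithelium, and crystallin transcripts took 32.8% ± 4.63 of all counts in sham and 35.1% ± 4.32 in ASC (n = 4 each; exact permutation p = 0.514). Library totals lay between 14420494 and 21141582 counts, 31455 genes had a count in any library and 15857 were tested.

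The comparison of ASC with sham asks how gene expression changes overall in this model of fibrotic cataract. Cxcl1 (ENSMUSG00000029380), a neutrophil-attracting chemokine, rose from 0.362 ± 0.601 to 23.0 ± 10.8 CPM (log2 fold change 5.88, SE 0.85, adjusted p = 0.0352), and Egr1 (ENSMUSG00000038418), an immediate early transcription factor, from 8.22 ± 7.11 to 349 ± 97.6 CPM (5.38, SE 0.73, adjusted p = 0.0327). The size of the Cxcl1 rise depended on sham 3, which held 26 of its sham reads: without it the log2 fold change was 8.21, and 5.47 to 5.58 without another sham library. Ccn1, a secreted matricellular protein, rose to 217 ± 23.8 CPM (log2 fold change 3.75, SE 0.31, adjusted p = 0.0021). Gdf15, a stress-induced cytokine of the TGF-beta superfamily, rose by 3.53. Gem, a small GTPase, and the nuclear receptor Nr4a1 rose by 3.48 each. The gamma crystallins Cryga (3.65) and Cryge (3.46) complete the 8 largest rises under the naming rule. The falls named by the rule were smaller than these rises, and the largest fall of any called gene was 3.90-fold. Ppp1r3c, a glycogen-targeting phosphatase subunit (-1.23), the zinc finger genes Zfp866 (-1.19), Zfp748 (-1.11) and Zfp719 (-0.85), the death receptor Tnfrsf25 (-1.15), the eye development gene Mab21l1 (-0.96), Rbm12b2 (-0.93) and the amylase Amy1 (-0.92) fell the most under that rule. Zfp748 lost its call without sham 1, sham 2, sham 3, ASC 1, ASC 3 or ASC 4 (adjusted p up to 0.104). Zfp719 lost it without sham 1, sham 2, sham 4, ASC 1, ASC 3 or ASC 4 (up to 0.0838). Rbm12b2 lost it without sham 2, sham 4 or ASC 4 (up to 0.078), and Amy1 without sham 1 or ASC 4 (up to 0.0546). Ppp1r3c, Zfp866, Tnfrsf25 and Mab21l1 kept theirs when any single library was left out. They lost it with the red cell or fibre level as a covariate. Ppp1r3c also lost it with the pigment level and without ASC 1 and ASC 4 together. Over all 25 alternatives Ppp1r3c was at -1.35 to -1.116, Zfp866 at -1.316 to -0.929 and Tnfrsf25 at -1.262 to -0.916.

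In all, 162 genes passed the threshold in edgeR's quasi-likelihood test, 100 higher and 62 lower in ASC, and 143 of them were protein-coding. At least a 2-fold change was seen for 92, of which 79 rose and 13 fell. The 4 ASC libraries lay on 1 side of the 4 sham libraries for all 162 genes, and for 9.06% of all tested genes, against 2.86% given by chance. An unadjusted p under 0.05 was reached by 2335 genes. Scaling by library totals alone gave 75 higher and 70 lower genes and moved the median log2 fold change of all genes from 0.008 to -0.116. The number of genes depended on the set of libraries, falling to 79, 56 or 67 without sham 1, sham 2 or sham 4 and to 101, 72 or 67 without ASC 1, ASC 3 or ASC 4. The count with at least a 2-fold change was 58, 44 or 49 without sham 1, sham 2 or sham 4. It was 143 without ASC 2, and 53 or 49 without ASC 3 or ASC 4.

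**Figure D1:**
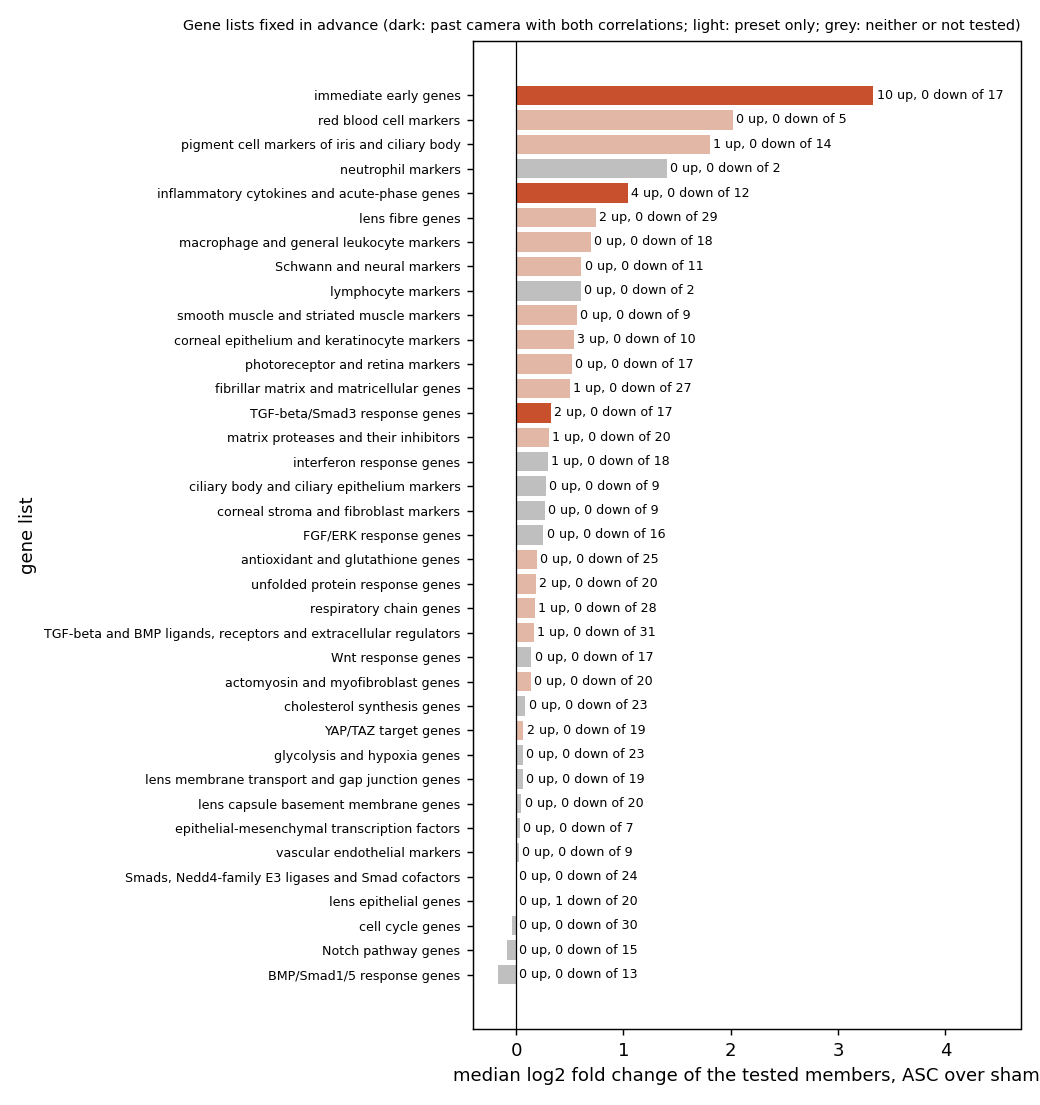
Bars show the median log2 fold change (ASC over sham) of the tested members of each of the 37 gene lists, with the number of members past the threshold beside each bar. The immediate early list has the highest median, 3.33, with 10 of 17 members higher, and the 24 Smads, Nedd4-family ligases and Smad cofactors have a median of 0.002 with 0 members past the threshold.

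Immediate early genes, the fast transcriptional responders to growth factors, stress and injury, moved together. Of 17 tested, 10 rose and 0 fell, and 16 rose when adjusted over the list alone. All 17 had a positive log2 fold change, with a median of 3.33 (camera adjusted p = 8.5e-70, and adjusted p = 0.0137 with an estimated correlation). Beside Egr1 and Nr4a1, Ier2 rose from 5.05 ± 1.16 to 54.1 ± 17.7 CPM (3.40, SE 0.30, adjusted p = 0.0021). Jun (ENSMUSG00000052684), named here after its values were seen, rose from 28.4 ± 3.13 to 259 ± 49.0 CPM (3.19, SE 0.15, adjusted p = 6.8e-07). Fos, also chosen after the values were seen, had 14.6 ± 23.9 CPM in sham and 342 ± 92.7 CPM in ASC. It did not pass edgeR's test but passed those of DESeq2 and limma-voom (4.53, SE 1.26, adjusted p = 0.19). Its log2 CPM was 5.66 in sham 3 and at most 1.95 in the other sham libraries. Corneal keratins also rose in ASC, and the summed red cell and pigment marker levels had higher means that did not pass adjustment (exact permutation tests, adjusted p = 0.171 and 0.206). With the summed red cell level as a covariate, added after seeing the data, 3 of the 17 genes remained past the threshold at a median of 3.34. The median SE grew from 0.442 to 0.586. The red cell level did not overlap between the groups (40.05 to 62.81 CPM in sham, 73.88 to 370.2 CPM in ASC). As a covariate it therefore cannot tell blood from the group itself. With the lens fibre level 2 of the 17 passed, at a median of 2.87. Egr1 lost its call without any of sham 1, sham 2, ASC 1, ASC 3 or ASC 4 (adjusted p up to 0.107) and Nr4a1 without sham 1, sham 2, ASC 1 or ASC 3 (up to 0.0878). Of the list, 6 genes passed without each of sham 1, sham 2, ASC 1 and ASC 3.

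**Figure D2:**
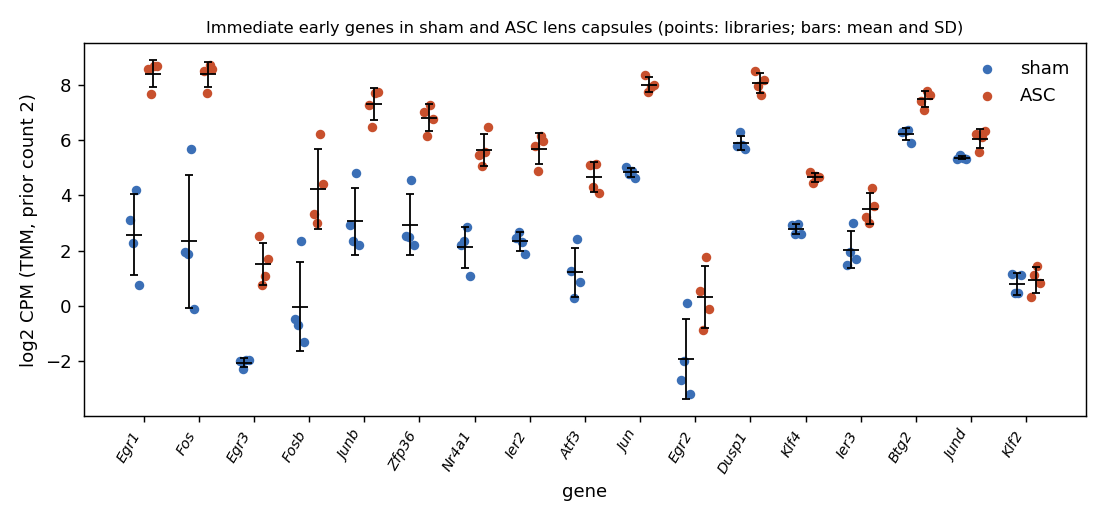
Log2 CPM of the 17 immediate early genes in each sham and ASC library (points), with the mean and SD of each group (bars), ordered by log2 fold change. The ASC libraries lie between 7.72 and 8.35 for Jun and the sham libraries between 4.64 and 5.01, while sham 3 reaches 5.66 for Fos.

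Inflammatory cytokines and acute-phase genes were the second list that held with both correlations. Of 12 tested members, 4 rose and 0 fell, and 5 rose adjusted over the list alone. The median was 1.04 (camera adjusted p = 6.3e-11, and adjusted p = 0.0178 with an estimated correlation). They were Cxcl1, the interferon-induced chemokine Cxcl10 (5.35, SE 0.72, adjusted p = 0.007), the monocyte chemokine Ccl2 (2.95, SE 0.46, adjusted p = 0.0425) and the prostaglandin synthase Ptgs2. Ptgs2 lies below the abundance limit of the naming rule and was chosen after its values were seen (4.60, SE 0.58, adjusted p = 0.0026). Ccl2 reached 108 ± 25.9 CPM in ASC. DESeq2 called 5 members, and limma-voom 2, Ccl2 and Ptgs2 without Cxcl1 and Cxcl10. With the pigment, red cell or fibre level as a covariate 1 member passed. The log2 fold change of Cxcl1 was 5.173 to 8.206 over all 25 alternatives. Sham counts of these genes were low, with at most 6 reads per sham library for Cxcl10 and 2 for Ptgs2. Cxcl1 lost its call without each library but sham 3 (adjusted p up to 0.103) and Ccl2 without each but sham 1 (up to 0.103). The list had 2 members past the threshold without sham 2, sham 4, ASC 1, ASC 2 or ASC 3. Of leukocyte markers, 0 of 18 macrophage and general leukocyte genes passed edgeR's test (2 at an unadjusted p under 0.05, 1 by DESeq2, 0 by limma-voom). Their median was 0.695 (camera adjusted p = 0.00056, and adjusted p = 0.419 with an estimated correlation). Their summed level was 72.3 ± 33.5 CPM in sham and 177 ± 77.3 CPM in ASC (exact permutation p = 0.0857). Gpnmb had 24.1 ± 16.3 and 102 ± 50.6 CPM (adjusted p = 0.222) and Lyz2 9.77 ± 4.36 and 16.1 ± 8.54 CPM (adjusted p = 0.634). Of the neutrophil and lymphocyte lists 2 members each were tested and 0 passed (1 and 0 at an unadjusted p under 0.05, 0 by the other tools). Adjusted over the list alone, 1 neutrophil marker rose. Ltf, Mmp9, Lck and Nkg7 averaged at most 1.55 CPM in both groups. The summed neutrophil level was 1.62 ± 0.617 CPM in sham and 3.97 ± 1.16 CPM in ASC (exact permutation p = 0.0286, the smallest possible, adjusted p = 0.171).

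None of the named Smads and Smurfs passed the test in edgeR, DESeq2 or limma-voom. Smurf1 (ENSMUSG00000038780), the E3 ubiquitin ligase that targets Smads and that the series is titled after, was at 23.4 ± 2.78 CPM in sham and 24.7 ± 2.06 CPM in ASC (log2 fold change 0.08, 95% confidence interval -0.16 to 0.31, adjusted p = 0.802). Smurf2 was at 51.2 ± 5.22 and 48.5 ± 5.39 CPM (-0.08, interval -0.31 to 0.16). Smad1 (0.24), Smad2 (-0.08), Smad3 (0.04), Smad4 (0.11), Smad5 (-0.15) and Smad7 (-0.10) had adjusted p-values of 0.488 or more. The abundant Nedd4 (0.02) and Ppm1a (0.14) did not pass either. Of the 24 Smads, Nedd4-family ligases and Smad cofactors 0 passed edgeR's test (2 at an unadjusted p under 0.05, 1 by DESeq2, 0 by limma-voom), with a median of 0.002 (camera adjusted p = 0.761). For change in either direction this list passed fry (adjusted p = 0.0159), as 1 of 23 among the 35 lists tested. Fry does not compare a list with other genes, and 2335 of all 15857 tested genes had an unadjusted p under 0.05. Its result therefore does not set this list apart from the other genes. The upper ends of these intervals, 0.60 for Smad1 and at most 0.31 for the other named Smads and Smurfs, bound any rise of the transcript. Protein levels and phosphorylation were not measured. Of 31 tested ligands, receptors and extracellular regulators of TGF-beta and BMP, Gdf15 alone rose (1 also adjusted over the list alone; camera adjusted p = 0.00083, and adjusted p = 0.291 with an estimated correlation). With the red cell or fibre level as a covariate 0 of these passed, while the log2 fold change of Gdf15 was 3.226 to 3.906 over all 25 alternatives. Tgfb1 (0.31, adjusted p = 0.34) and Tgfb2 (0.05, adjusted p = 0.89) did not pass. Of 13 BMP/Smad1/5 response genes 0 passed (3 at an unadjusted p under 0.05, 0 by DESeq2 or limma-voom; median -0.165, camera adjusted p = 0.19), with Id3 at 0.25 and Id2 at -0.06.

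**Figure D3:**
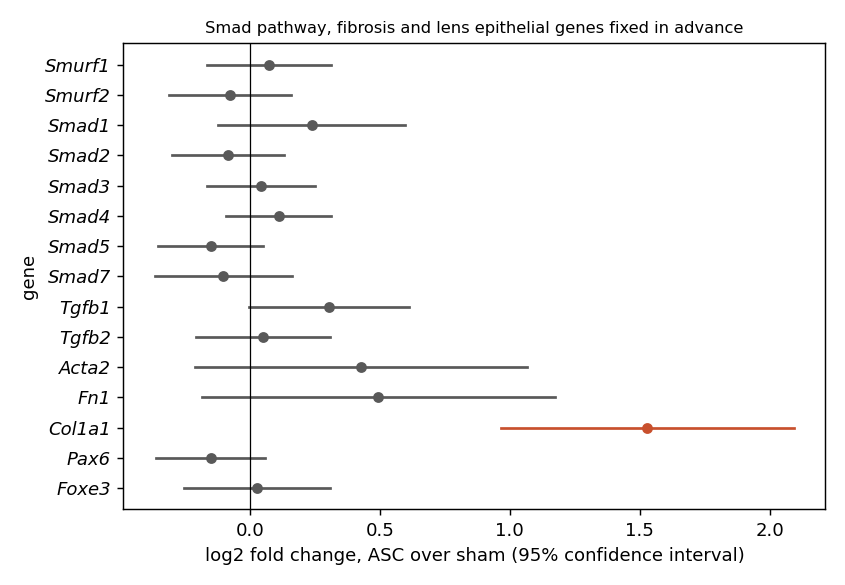
Log2 fold changes (ASC over sham, points) with 95% confidence intervals (lines) for the 15 genes named whatever their result. The interval of Col1a1, 0.97 to 2.09, is the one above 0, and that of Smurf1 runs from -0.16 to 0.31.

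Genes that TGF-beta induces through Smad3 passed the list test with few members past the threshold. Of 17 tested, 2 rose and 0 fell, and 7 rose adjusted over the list alone. The median was 0.33 (camera adjusted p = 2.2e-05, and adjusted p = 0.0446 with an estimated correlation). The pair was Col1a1 (ENSMUSG00000001506), a chain of type I collagen, which rose from 1.55 ± 0.434 to 4.51 ± 0.469 CPM (1.53, SE 0.26, adjusted p = 0.0186), and Bhlhe40. Bhlhe40, a transcription factor that also answers hypoxia and clock signals, rose from 36.0 ± 12.3 to 97.2 ± 16.2 CPM (1.43, SE 0.23, adjusted p = 0.0327). Junb, an immediate early gene, is a member of both lists. Of the 18 response genes 10 are also on other lists, and the list was not tested without them. Its result can therefore not be set apart from the rise of the immediate early genes. A positive log2 fold change was seen for 12 of the 17 tested, and Smad7 stood at -0.10. Among 27 fibrillar matrix and matricellular genes Col1a1 rose and 0 fell, and 2 rose adjusted over the list alone. DESeq2 called 4 of them, Thbs1, Col8a1, Tgfbi and Col1a1, and limma-voom Col1a1. The median was 0.505 (camera adjusted p = 5.8e-05, and adjusted p = 0.25 with an estimated correlation). Fn1, fibronectin, had 4.86 ± 2.43 CPM in sham and 6.89 ± 1.04 CPM in ASC (0.49, adjusted p = 0.497). Col1a1 lost its call without sham 4, ASC 3 or ASC 4 (adjusted p up to 0.0605). Bhlhe40 lost it without sham 1, sham 2, sham 4, ASC 1, ASC 3 or ASC 4 (up to 0.109). The response list had 0 members past the threshold without sham 4, ASC 3 or ASC 4, and 1 without sham 1, sham 2 or ASC 1. Beside the corneal, pigment and red cell markers given below, 0 members passed with the pigment or red cell level as a covariate, and Col1a1 did not pass with the pigment, red cell or fibre level. The log2 fold change of Col1a1 nevertheless stayed between 1.317 and 1.785 over all 25 alternatives.

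No tested member of the actomyosin and myofibroblast list or of the epithelial-mesenchymal transcription factor list passed edgeR's gene test. Of the 12 transcription factors on the latter list 7 had enough counts to be tested. Of 20 actomyosin and myofibroblast genes 0 passed (6 at an unadjusted p under 0.05, 1 by DESeq2, 0 by limma-voom; median 0.14, camera adjusted p = 0.0014, and adjusted p = 0.121 with an estimated correlation). As a list they passed fry as higher in ASC (adjusted p = 0.0212). A positive log2 fold change was seen for 19 of the 20, and for 11 when scaled by library totals alone. Acta2, smooth muscle actin, had 180 ± 43.1 CPM in sham and 242 ± 83.5 CPM in ASC (0.43, interval -0.21 to 1.06, adjusted p = 0.527). Vimentin (Vim) had 3100 ± 351 and 3458 ± 428 CPM (0.16), with Itgb1 at 0.05. Of 7 tested epithelial-mesenchymal transcription factors 0 passed (0 also at an unadjusted p under 0.05 and by the other tools; camera adjusted p = 0.909), with Zeb2 at -0.12 and Tcf4 at 0.03. Of 20 matrix proteases and inhibitors 1 rose, the urokinase gene Plau (3.16, adjusted p = 0.0056), chosen after its values were seen, with 2 to 10 reads per sham library. With the pigment, fibre or retina level as a covariate 0 of these passed. Adjusted over the list alone 5 rose (camera adjusted p = 0.00013, and adjusted p = 0.267 with an estimated correlation). The abundant Ctsl (-0.04) and Timp2 (0.16) did not pass. Of 20 basement membrane genes of the lens capsule 0 passed (0 at an unadjusted p under 0.05 and by the other tools; camera adjusted p = 0.648). Col4a1 had 7274 ± 826 CPM in sham and 7318 ± 1380 CPM in ASC. Cell cycle genes showed 0 of 30 past the threshold (1 at an unadjusted p under 0.05, 0 by the other tools; median -0.035, camera adjusted p = 0.738), with Ccnd1 at -0.05 and Pcna at 0.06.

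Lens genes were tested as an epithelial and a fibre list. Among 29 fibre genes 2 rose and 0 fell, and 7 rose adjusted over the list alone. A positive log2 fold change was seen for 28, with a list median of 0.743 (camera adjusted p = 1.1e-12, and adjusted p = 0.26 with an estimated correlation). Cryga (ENSMUSG00000044429) rose from 3.18 ± 1.06 to 39.5 ± 20.2 CPM (3.65, SE 0.48, adjusted p = 0.0243) and Cryge from 43.4 ± 15.0 to 478 ± 208 CPM (3.46, SE 0.46, adjusted p = 0.0254). Both are gamma crystallins of differentiated fibre cells with closely similar sequences, so the share of each is uncertain. Cryaa, the most abundant transcript, took 14.8% ± 1.59 of counts in sham and 14.4% ± 2.09 in ASC. Of 20 epithelial genes 1 fell, Mab21l1 (ENSMUSG00000056947), from 147 ± 19.2 to 75.3 ± 7.89 CPM (-0.96, SE 0.11, adjusted p = 0.0021; 1 also adjusted over the list alone). The list median was -0.002 (camera adjusted p = 0.201). Pax6, the master regulator of eye development, had 455 ± 20.3 and 410 ± 20.7 CPM (-0.15, adjusted p = 0.502) and Foxe3, a lens epithelial transcription factor, 329 ± 11.8 and 335 ± 61.0 CPM (0.03, adjusted p = 0.952). Among 19 lens transport and gap junction genes 0 passed (1 at an unadjusted p under 0.05, 0 by the other tools; camera adjusted p = 0.567), with Mip at 0.07. Cryga lost its call without sham 1, sham 2, sham 3, sham 4, ASC 3 or ASC 4 (adjusted p up to 0.0835), and Cryge without each library but ASC 3 (up to 0.0883). Of the fibre list, 0 genes passed without any of sham 1, sham 2, sham 3, sham 4 or ASC 4, 1 without ASC 1 or ASC 3, and 6 without ASC 2. DESeq2 called 10, and limma-voom 2 others, without Cryga and Cryge. With the pigment, red cell or retina level as a covariate 0 fibre genes passed. Over 24 alternatives each, the log2 fold change was 2.015 to 3.999 for Cryga and 2.586 to 3.877 for Cryge. The fall of Mab21l1 did not pass with the red cell or fibre level, and its log2 fold change was -1.105 to -0.803 over all 25 alternatives.

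**Figure D4:**
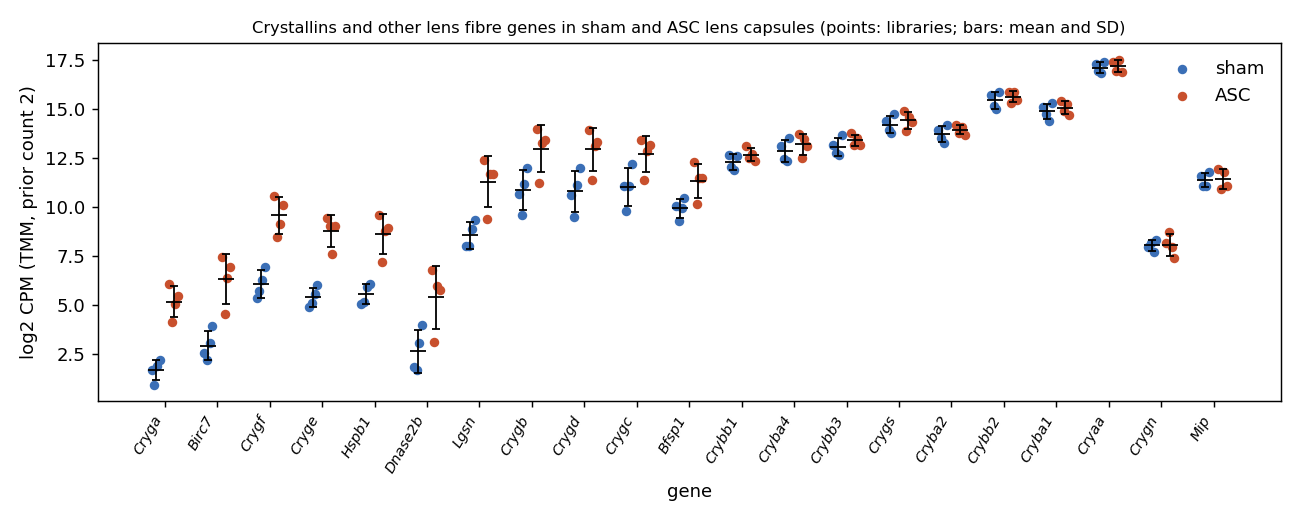
Log2 CPM of the crystallins on the lens fibre list and of Birc7, Lgsn, Dnase2b, Hspb1, Bfsp1 and Mip in each sham and ASC library (points), with the mean and SD of each group (bars), ordered by log2 fold change. The largest differences are on the left, 3.65 for Cryga, and the abundant Cryaa lies at the same level in both groups.

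Of the other signalling and metabolic lists, YAP/TAZ targets had 2 of 19 higher, Ccn1 and the stress gene Gadd45b (1.53, SE 0.22, adjusted p = 0.0147). Their median was 0.07 (2 also adjusted over the list alone; camera adjusted p = 0.0224, and adjusted p = 0.361 with an estimated correlation). Gadd45b lost its call without sham 1, sham 2, sham 4 or ASC 4 (adjusted p up to 0.0763). Unfolded protein response genes had 2 of 20 higher, the transcription factor Atf3 (3.33, SE 0.51, adjusted p = 0.0352) and the chaperone cofactor Dnajb9 (0.65, SE 0.12, adjusted p = 0.0327). Atf3 is also on the immediate early list. Adjusted over the list alone 3 rose (camera adjusted p = 9.1e-05, and adjusted p = 0.30 with an estimated correlation). Atf3 lost its call without each library but sham 3 (adjusted p up to 0.108) and Dnajb9 without sham 1, sham 3, sham 4, ASC 1 or ASC 3 (up to 0.0926). Interferon response genes had 1 of 18 higher, Irf1 (from 10.3 ± 2.19 to 45.2 ± 13.2 CPM, 2.13, SE 0.25, adjusted p = 0.0057). Adjusted over the list alone 1 rose and 2 fell (camera adjusted p = 0.149). Irf1 did not pass with the pigment, red cell or fibre level as a covariate, or without ASC 1 and ASC 4 together. Respiratory chain genes had 1 of 28 higher, Ndufa4 (0.54, SE 0.11, adjusted p = 0.0424). The count was 3 when adjusted over the list alone (median 0.17, camera adjusted p = 0.00019, and adjusted p = 0.361 with an estimated correlation). Ndufa4 lost its call without sham 1, sham 2, sham 3, ASC 1, ASC 3 or ASC 4 (adjusted p up to 0.115). With the red cell or fibre level as a covariate 0 members of these 4 lists passed, while the log2 fold change of Ccn1 was 3.481 to 4.071 over all 25 alternatives. With the pigment level 1 YAP/TAZ target did, and with the retina level 1 member each of the YAP/TAZ, unfolded protein and interferon lists.

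In edgeR's test 0 genes passed in 6 further lists. FGF/ERK response genes had 0 of 16 (6 at an unadjusted p under 0.05, 3 by DESeq2 and 1 by limma-voom; adjusted over the list alone 2 rose and 1 fell; camera adjusted p = 0.0503). The receptor Epha2 stood at 0.48 (adjusted p = 0.0709) and Etv5 at 0.07. Notch pathway genes had 0 of 15 (4 at an unadjusted p under 0.05, 3 by DESeq2 and 1 by limma-voom; adjusted over the list alone 4 fell; camera adjusted p = 0.0503). Lfng stood at -0.39 (adjusted p = 0.0983) and Notch2 at 0.08. Wnt response genes had 0 of 17 (2 at an unadjusted p under 0.05, 0 by the other tools; camera adjusted p = 0.176), with Dkk3 at 0.07 and Sfrp1 at -0.04. Glycolysis and hypoxia genes had 0 of 23 (2, and 1 by DESeq2; camera adjusted p = 0.716), with Pkm at 0.15 and Eno1 at -0.03. Their median of 0.063 and mean of -0.012 differ in sign. Cholesterol synthesis genes had 0 of 23 (3, and 0 by the other tools; camera adjusted p = 0.488), with Insig1 at 0.41 and Srebf2 at 0.10. Antioxidant and glutathione genes had 0 of 25 (5, and 3 by DESeq2; 1 adjusted over the list alone; median 0.19, camera adjusted p = 0.0018, and adjusted p = 0.121 with an estimated correlation), with Gstm1 at 0.01 and Gpx3 at 0.46.

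Transcripts of neighbouring eye tissues and blood were present, and few of their markers passed the test. Of 10 corneal epithelium and keratinocyte markers 3 rose, Krt5 (3.52, SE 0.60, adjusted p = 0.0387), the cornea-specific keratin Krt12 (3.19, SE 0.61, adjusted p = 0.0395) and the less abundant Krt6a (2.79, adjusted p = 0.0426), the latter chosen after its values were seen. When adjusted over the list alone 4 rose (camera adjusted p = 1.9e-07, and adjusted p = 0.121 with an estimated correlation). Krt5 lost its call without sham 2, sham 3, sham 4, ASC 1, ASC 3 or ASC 4 (adjusted p up to 0.135) and Krt12 without sham 2, sham 3, ASC 1, ASC 3 or ASC 4 (up to 0.13). The list had 0 members past the threshold without sham 2, sham 3, ASC 1, ASC 3 or ASC 4, and 1 without sham 4. It had 0 with the pigment, red cell or fibre level as a covariate. Of 14 pigment cell markers of iris and ciliary body 1 rose, Gpr143 (3.58, adjusted p = 0.0254), chosen after its values were seen, with at most 5 reads per sham library. The pigment count was 7 by DESeq2, 0 without any of sham 1, sham 2, sham 3, sham 4, ASC 3 or ASC 4, 4 without ASC 1 and 2 without ASC 2. A further count, adjusted over the list alone, was 9 higher, with a median of 1.80 (camera adjusted p = 2.6e-10, and adjusted p = 0.196 with an estimated correlation). The summed levels were 290 ± 87.8 and 598 ± 257 CPM (exact permutation p = 0.0571). Dct (1.74) and Trpm1 (0.24) did not pass. Red blood cell markers had 0 of 5 past the threshold (5 at an unadjusted p under 0.05, 4 by DESeq2, 0 by limma-voom) and 5 adjusted over the list alone (camera adjusted p = 1.3e-06, and adjusted p = 0.181 with an estimated correlation). Their summed level was 53.8 ± 10.5 CPM in sham and 218 ± 143 CPM in ASC (exact permutation p = 0.0286, the smallest possible, adjusted p = 0.171 over 12 marker sums). As a share of unscaled counts the same comparison gave an exact permutation p of 0.0571. Hbb-bs stood at 2.06 (adjusted p = 0.176) and Hba-a1, whose near-identical copy makes its share uncertain, at 1.94.

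Photoreceptor and retina markers had 0 of 17 past the threshold (2 at an unadjusted p under 0.05, 0 by the other tools; median 0.52, camera adjusted p = 0.00032, and adjusted p = 0.431 with an estimated correlation), with Gnat1 at 354 ± 248 and 599 ± 170 CPM. The summed retina level was 5040 CPM in sham 3 and 1253 to 2483 CPM in the other sham libraries, against 2397 CPM in ASC 1 and 3723 to 4491 CPM in the other ASC libraries. Without sham 3 and ASC 1 together 6 of the 17 retina markers passed as higher in ASC, with 7 pigment, 3 neural and 2 macrophage markers. Sham 3 had the highest summed retina, pigment and macrophage levels of the sham libraries, and ASC 1 the lowest of the ASC libraries. Leaving out both therefore favours these markers as higher in ASC, and their passing there is no evidence of a rise with the injury. Smooth and striated muscle markers had 0 of 9 (3 at an unadjusted p under 0.05, 1 by DESeq2, 0 by limma-voom; 1 adjusted over the list alone; camera adjusted p = 0.0069, and adjusted p = 0.121 with an estimated correlation). Synm stood at 0.07. Myh11 (3.65, adjusted p = 0.131) passed when ASC 3 was left out (adjusted p = 0.0173). Neural markers had 0 of 11 (2, and 2 by DESeq2; 2 adjusted over the list alone; camera adjusted p = 0.0073, and adjusted p = 0.361 with an estimated correlation), with Pmp22 at 0.02 and Snap25 at 0.61. The ciliary epithelium (0 of 9; 1 at an unadjusted p under 0.05; camera adjusted p = 0.738), corneal stroma (0 of 9; 2, and 1 by DESeq2; camera adjusted p = 0.196) and vascular endothelium (0 of 9; 0; camera adjusted p = 0.682) lists had 0 members past the threshold. Their abundant members were Optc at 0.17, Car14 at -0.12, Ptgds at 0.62, Ogn at 0.14, Flt1 at -0.01 and Egfl7 at 0.03.

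**Figure D5:**
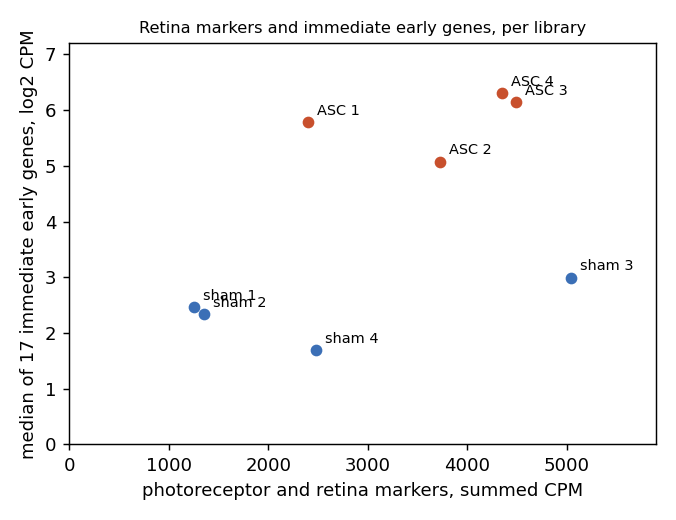
Each point is 1 library, with the summed CPM of the photoreceptor and retina markers on the x axis and the median log2 CPM of the 17 immediate early genes on the y axis. The immediate early median is at most 2.99 in the sham libraries and at least 5.08 in the ASC libraries, while the retina level of sham 3, 5040 CPM, is above those of all ASC libraries.

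Over 35 lists, 19 passed camera with the preset correlation, all of them upward, and 3 with an estimated one: immediate early, inflammatory and TGF-beta/Smad3 response genes. By fry, which does not compare a list with other genes, 7 lists passed in 1 direction and 23 in either direction. The latter held 8 lists that did not pass camera: Smads and ligases, BMP response (adjusted p = 0.0276), lens epithelial (5.2e-05), FGF/ERK (0.00048), Wnt (0.035), Notch (5.2e-05), interferon (2.1e-05) and corneal stroma genes (0.0297). On principal components of log2 CPM, PC1 held 31.7% of the variance and did not separate the groups (exact permutation p = 0.0571). With the 500 most variable genes PC1 held 41.1% and the exact permutation p was 0.0286, the smallest possible. On PC1 of all tested genes sham 3 (9.35) and ASC 1 (-6.85) lay on the side of the other group. PC2 held 20.2% (exact permutation p = 0.0857). Spearman correlations across genes averaged 0.978 within groups and 0.971 between them, and no pair of libraries of the same group was close enough to be the same library deposited again.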

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

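These checks were fixed before the data were examined. Among 80 groups of 4 values, 4 held a library standing far from the other libraries of its group, and 4 are expected by chance. Egr1 in ASC 2 had a log2 CPM of 7.67, below the 8.57 to 8.67 of the other ASC libraries, and still above each sham library. Smurf2 in sham 1 had 5.44, below the 5.74 to 5.77 of the other sham libraries. Smad3 in sham 4 had 5.78, with the other sham libraries at 5.92 to 5.94. Fn1 in ASC 1 had 2.45, with the other ASC libraries at 2.87 to 2.95.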

How the results depend on the processing

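Marker covariates, GC and length corrections and the 2 sets of left-out libraries were chosen after seeing the data. The red cell level did not overlap between the groups, so calls lost with it as a covariate cannot tell blood from the group itself. The genes of the first 2 parts of the naming rule gave 773 results under the alternatives. Of these, 654 stayed on their side of the threshold, 119 results of the 17 called genes lost the call, 0 were newly called and 0 were reversed. The 654 include the genes not called in the main fit, such as Smurf1 with 25 of 25, which stayed uncalled throughout. Called genes kept the call in between 9 of 24 alternatives (Cryge) and 23 of 25 (Gem among others). Smurf1, Smurf2 and the 6 named Smads passed in 0 of 25 alternatives each, DESeq2 and limma-voom among them. The 162 genes became 593 with DESeq2 (336 higher, 257 lower; 162 shared), 712 without a low-count filter (162 shared), 29 against a 1.5-fold null, and 44 at an adjusted p under 0.01. They became 55 with the pigment level as a covariate, 12 with the red cell level, 16 with the lens fibre level and 59 with the retina level, for which the cause was not tested. They became 42 without ASC 1 and ASC 4 (fewer samples), and 340 without sham 3 and ASC 1 (112 shared; 6 photoreceptor, 7 pigment, 3 neural and 2 macrophage markers among them, against 0, 1, 0 and 0), for which the cause was not tested. Sham 3 had the highest retina, pigment and macrophage levels of the sham libraries, and ASC 1 the lowest of the ASC libraries. Leaving out both therefore favours those markers as higher in ASC. Leaving out 1 library gave 56 to 228 genes (109 without sham 3, 228 without ASC 2). The 92 genes with at least a 2-fold change became 260 with DESeq2 and 303 without a filter, and 44 to 143 when 1 library was left out, with 58, 44 and 49 without sham 1, sham 2 and sham 4, 53 and 49 without ASC 3 and ASC 4, and 143 without ASC 2. For DESeq2 and the filter the cause was not tested. Lists past camera fell from 19 to 3 with an estimated correlation. The exact permutation p of PC1 went from 0.0571 to 0.0286 with the 500 most variable genes. Other scalings and limma-voom left the counts within 1.5 times.

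Replicate numbers did not pair the libraries: deviations of equal numbers correlated at 0.217, 0.0573, 0.214 and -0.0897, and not every library correlated best with its own number. The replicate block gave 169 genes (130 higher, 39 lower; 108 shared). The count of 10 immediate early genes became 15 with DESeq2, 6 to 13 without 1 library, 6 against a 1.5-fold null, 5 without ASC 1 and ASC 4, 6 with the retina level and 3 with the red cell level as a covariate. Small changes were often missed at this depth and number of replicates, neither of which was varied: simulated 1.5-fold changes were called in 30.3%.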

Other observations

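The genes in this paragraph and the next were chosen after their values were seen. Nfkbia, an inhibitor of NF-kB, rose from 19.7 ± 2.74 to 110 ± 27.3 CPM (log2 fold change 2.48, adjusted p = 6.6e-05), and its relative Nfkbiz from 15.9 ± 1.38 to 65.3 ± 16.5 CPM (2.04, adjusted p = 0.00028). Ppp1r15a, a phosphatase subunit of the integrated stress response (2.18, adjusted p = 5.6e-06), the DNA damage-inducible gene Gadd45a (1.75, adjusted p = 0.0352), the small Maf protein Maff (1.44, adjusted p = 6.6e-05), Csrnp1 (2.79, adjusted p = 9.9e-06) and the acute-phase regulator Cebpb (1.73, adjusted p = 0.007) rose as well. The mitochondrial 16S ribosomal RNA mt-Rnr2, which poly-A selection recovers in part, rose from 313 ± 61.1 to 664 ± 58.8 CPM (1.08, adjusted p = 0.003), while all mitochondrial genes together took 1.87% ± 0.293 of counts in sham and 2.04% ± 0.131 in ASC (exact permutation p = 0.371).

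Among single genes that fell were Tra2a (-0.56, adjusted p = 0.0138), Clk1 (-0.52, adjusted p = 0.0254) and Luc7l3 (-0.49, adjusted p = 0.0426). Per1, a clock gene that stress signals also induce, rose by 1.14 (adjusted p = 0.0021), and the clock genes Dbp (0.10), Nr1d1 (-0.10), Per2 (-0.01) and Per3 (-0.18) did not pass.

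The tests below with pigment and fibre covariates, of handling, of gamma crystallin genes and of the exchange of 2 libraries were chosen after the results were seen. The other splits of the libraries were planned. Zinc finger genes named Zfp, noticed among the falls, made up 13 of the 62 genes that fell and 2.26% of tested genes, which was not tested on other data. Of 358 tested, 287 had a negative log2 fold change, with a median of -0.276. Of the 13 that fell, 9 and 10 still did after the GC and length trends were removed. Of all tested Zfp genes, between 3 and 6 passed when any library but ASC 2 was left out, and 0 with the red cell or fibre level as a covariate.

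Immediate early genes were higher in ASC by a median of 3.33 on the log2 scale (median SE 0.442). Pigment cells and remaining fibre cells are argued against as whole causes: with the pigment level as a covariate the median was 2.75 (median SE 0.544) and 7 genes passed, and with the fibre level 2.87 (median SE 0.813) with 2 passing, the calls ending as SEs grew. Time or handling between death and RNA extraction may contribute, and the test of it cannot decide. The list median of the between-sham SD was above that of every one of 10000 matched lists (percentile 100). Those lists were matched on mean expression over all 8 libraries. Immediate early genes were lower in sham, so they were set against genes more abundant there. No sham library reached the ASC range, and the labels name no order of collection, so handling and the injury itself cannot be told apart here.

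Gamma crystallins a to f and late fibre genes such as Birc7, Lgsn and Dnase2b had higher means in ASC, of which Cryga and Cryge passed the test. Reads shuffled between gamma crystallin copies would leave their sum level. The sum was higher by 2.04 (SE 0.717), although its exact permutation p of 0.0571 did not pass. Crygb, Crygc and Crygd make up most of it, at a log2 CPM of at least 9.48 in each library. Cryga reached at most 6.04 and Cryge 9.42. The sum therefore cannot decide whether reads of the abundant copies were counted for Cryga or Cryge. Left open, and not tested, are more fibre cells on the ASC capsules, as a candidate explanation from the preparation, and fibre cells newly formed after capsule injury.

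The 35 splits of the 8 libraries into 4 and 4 do not exclude chance for the counts at the 0.05 level. For the 162 genes 2 splits gave as many, the highest other being 309; for the 92 genes with a 2-fold change 2 did (highest other 218), and for the 19 lists 3 did (highest other 20). The split with 309 genes exchanges sham 3 and ASC 1, and shared 0 genes with the groups as labelled, while the remaining 33 splits called at most 6, which points to a second structure in the libraries. Retinal tissue carried along in sham 3 and ASC 2 to 4 may account for part of it: 9 of 17 photoreceptor and retina genes were higher there (Fisher exact p = 6.4e-12, median 1.19), and 0 immediate early genes passed. That p treats markers that move together as independent, so it overstates the evidence. Of 11 neural markers 4 passed too, as did Postn (2.06), Spp1 (1.85) and Cdh11 (1.35) of the matrix and myofibroblast lists. Summed pigment and macrophage levels were also higher in sham 3 (404 and 113 CPM) than in ASC 1 (306 and 64.2 CPM). A swap of these 2 labels as the only structure is argued against by the 162 genes called with the labels as given, far above 6.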
